A study of Danio rerio with 4 samples.

How the data were processed

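Single cells from zebrafish brain were profiled with Drop-seq, a droplet method that captures the 3' ends of transcripts on barcoded beads, per the labels' protocols. There were 4 libraries, 1 per group: wild type at 5 days post fertilization (dpf), scn1Lab homozygous mutant at 5 dpf, scn1Lab mutant at 8 dpf and wild type at 8 dpf. Sequencing was done on a NextSeq 500, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.0, STAR without a version, and the genome build GRCz11. The gene annotation, the choice of barcodes and the collapsing of molecular identifiers are not given in the sources used here.

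The deposited values are whole-number counts per gene and cell barcode, with no normalization, per the file headers and the values themselves. They are read as counts of unique molecular identifiers (UMIs) because the protocol is Drop-seq and the files have the form of its digital expression matrix. Each library listed 3000 barcodes of 12 bases. The libraries listed 21571 genes (wild type, 5 dpf), 20707 (mutant, 5 dpf), 21337 (mutant, 8 dpf) and 21446 (wild type, 8 dpf), with 24493 in their union. Genes are identified by symbol only. Barcodes that shared their first 11 bases with another numbered 159, 46, 113 and 69 in that order, and were not merged, so some cells may be listed more than once.

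A barcode was kept as a cell with at least 300 UMIs, at least 200 genes and at most 25% of UMIs on mitochondrially encoded genes. The mitochondrial limit removed 0 barcodes, but with the remaining UMIs of the mitochondrial contig counted too, 199, 62, 161 and 152 of the cells kept would exceed it in the order above. Cells kept numbered 1234, 725, 889 and 940 in the same order of libraries, with medians of 1174, 892, 1110 and 715.5 UMIs and 552, 467, 449 and 352 genes per cell. Scrublet, as built into scanpy, called only 1, 1, 0 and 1 cells as doublets, too few to serve as a caller at this depth, so no doublets were removed in the main analysis. Removing the 5% of cells with the highest doublet score was run as an alternative.

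UMIs were summed over the kept cells of each library and divided by the library total to give CPM, counts per 1e6 UMIs. A gene was compared when it had at least 100 UMIs over both libraries, and a member of a gene list at 20. With 1 library per group there is no replicate, so no test was run and no p-value is given. Counts of genes are counts by size, a ratio of at least 2 or at most 0.5. Ratios carry exact conditional 95% intervals, levels exact Poisson intervals and shares exact Clopper-Pearson intervals. All intervals and limits cover counting error only, not the difference between animals or between preparations. Intervals of ratios, levels and lists treat each UMI as an independent draw, so they also leave out the sampling of cells. They are too narrow, even for the same library, where few barcodes hold most UMIs of a gene. A gene with 0 UMIs in 1 library is given as "at least" a fold, against a floor of 3 counts in that library. This fold is not the bound of the exact 95% interval, which lies nearer to 1. For prl between the ages in the mutant the interval's bound is 267-fold, against 329-fold by the floor.

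A total of 26 gene lists were fixed before the data were examined, together with the comparisons, the marker sets and most alternatives. A list's value is its median log2 ratio, with an interval from 1000 Poisson redraws of the counts, and the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a p-value. All 26 lists were computed at both ages, and which of them lead the report was chosen after their values had been seen. A list member with 0 UMIs in 1 library enters at its bound. The named genes are, for each comparison and direction, the 10 whose nearer interval bound lies furthest from 1. Genes with clone-based names, mitochondrially encoded genes and cytosolic ribosomal protein genes are left out of that ranking. The rule names 5 genes per direction within a cell class and between ages, and up to 4 members per list. scn1lab is always given. All 10 genes per direction are printed for each age and for both ages, while of the list members and the genes within cell classes only some are printed, picked after their values were seen.

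Cells of the 4 libraries were clustered together on log-normalised values of 2000 variable genes, centred within each library. The clustering used 30 principal components, 15 neighbours and Leiden clustering at resolution 1, with seed 0. It gave 34 clusters, and 36 after 1 of them was split at resolution 0.5. A cluster was named when at least 3 markers from 1 of 24 marker sets were at least 2-fold higher in it and present in at least 10% of its cells. The set with the most such markers gave the name, with the sets of neuron subtypes merged into 1 neuron-like class. A tie left the cluster unnamed, as with cluster 31, and so did 10 leading genes that held more markers of another class, as with cluster 35, which had 11 neuron markers but was led by digestive genes. Clusters with at least 2 genes of olfactory neurons, Schwann cells or meninges among their 15 leading genes were also left unnamed, a rule added after the clusters were seen. Cell classes with at least 50 cells in each library were compared separately. The software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9.

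The comparison was tested on simulated data drawn from the real means and library sizes, with 200 genes altered by known folds. Counts were Poisson draws per gene and library, the same model as the intervals, with no clumping of UMIs in cells and no difference between preparations. The simulation therefore checks the computation only, and does not show how many 2-fold genes of the real data arise without a genotype difference. Intervals covered the true ratio for 96.0% of 5458 genes at 5 dpf, 96.0% of 4147 at 8 dpf, 95.2% of 5560 for age in wild type and 95.6% of 4204 for age in the mutant. In the 5 dpf simulation 100% of 4-fold genes, 54.8% of 2-fold genes and 3.33% of 1.5-fold genes were counted as 2-fold. In the 8 dpf simulation these were 100%, 40.0% and 1.56%. Of 5276 and 3976 unaltered genes, 2 and 0 were counted. Of 200 simulated lists without a difference, 4.5% at 5 dpf and 5.5% at 8 dpf fell outside the central 95%, and 100% of lists given a 2-fold difference lay above it.

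Alternatives covered the cell filter, the scaling, the UMI minimum, the summary of a list, clustering resolution and seed, doublet scores, centring, depth and re-weighting of each library to equal class shares. Settings added after the data were seen are the libraries without barcodes over 10000 UMIs, each cell weighted equally, the filter with the mitochondrial contig counted, and shares among named classes only. The windows by gene order around scn1lab were also added then. Windows in megabases were not used, because the gene table at hand is of assembly GRCz12tu and the counts are of GRCz11. Neighbours are therefore given by gene order in GRCz12tu and no coordinates are printed. A ratio of GABAergic to glutamatergic cell classes was left out because no cluster could be named as glutamatergic.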

Results

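The data are counts of transcripts in single cells from zebrafish brain, from wild-type fish and from fish homozygous for a mutation in scn1Lab, the zebrafish gene for a voltage-gated sodium channel alpha subunit used to model Dravet syndrome. Each genotype was sampled at 5 and at 8 dpf, with 1 library per group and so no replicates anywhere. The libraries held 3525002 UMIs (wild type, 5 dpf), 1965005 (mutant, 5 dpf), 2525205 (mutant, 8 dpf) and 2378193 (wild type, 8 dpf), of which 3156760, 1610612, 2071321 and 1910716 lay in the cells kept. A few very large barcodes weighed heavily in every library. Barcodes over 10000 UMIs numbered 45, 23, 28 and 24 and held 38.2%, 37.8%, 36.3% and 40.9% of the UMIs in kept cells. Mitochondrially encoded genes took 1.44%, 1.47%, 1.60% and 1.90% of UMIs and ribosomal protein genes 16.8%, 17.0%, 20.5% and 21.3%, in the same order of libraries. Every difference below is therefore between 2 libraries and has no replicate check.

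The targeted gene itself was rare. scn1lab had 16 UMIs in wild type at 5 dpf (5.07 CPM, interval 2.90 to 8.23), 8 in the mutant at 5 dpf (4.97 CPM, 2.14 to 9.79), 9 in the mutant at 8 dpf (4.35 CPM, 1.99 to 8.25) and 20 in wild type at 8 dpf (10.5 CPM, 6.39 to 16.2). The ratio of mutant to wild type was 0.980 at 5 dpf (0.363 to 2.43), so a difference was not detectable at this depth, and 0.415 at 8 dpf (0.166 to 0.954). The labels do not say what the mutation is or whether it lowers the transcript, so these counts neither support nor contradict the genotype labels. In neuron-like cells alone scn1lab had 7, 5, 2 and 6 UMIs, and the 5 dpf ratio was 2.44.

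The comparison at 5 dpf asks how the mutant brain differs from wild type at the earlier of the sampled ages. Synaptic vesicle, GABA and glutamate receptor genes were lower in the mutant library. Of 21 synaptic vesicle and release genes, 18 were lower, with a median log2 ratio of -0.60 (-0.75 to -0.45), below all 10000 matched random lists. Over the cells outside clusters 6, 34 and 35 the median was -0.083 (-0.23 to 0.16), so the difference was not seen there. The vesicle proteins sypa (ratio 0.240, 0.141 to 0.388) and sv2a (0.282, 0.167 to 0.452) were among the lowest. Genes for GABA synthesis, loading and uptake were lower in 6 of 7 cases (median -0.85, -1.11 to -0.49, percentile 0.03). Among them were gad1b and gad2, which make GABA, at 0.441 (0.249 to 0.742) and 0.526 (0.394 to 0.693), and the GABA transporter slc6a1b at 0.462 (0.386 to 0.550). Since gad1b is a leading gene of cluster 6, with 39 wild-type and 8 mutant cells, this difference too may follow the number of such cells captured. Ionotropic glutamate receptor genes were lower in 10 of 13 cases (median -0.97, -1.39 to -0.42, percentile 0.305), with gria1a at 0.401 (0.227 to 0.671).

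Progenitor and microglial genes were higher in the same comparison. The neurogenesis and progenitor list had a median of 0.42 (0.30 to 0.50), above all random lists, with 21 of 28 members higher. Its leading members were the Notch-responsive her12 at 6.93-fold (5.18 to 9.39) and her4.4 at 4.25-fold (3.62 to 4.99). The microglia and inflammation list had a median of 0.63 (0.41 to 0.82, percentile 99.98), with apoc1 at 3.05-fold (2.65 to 3.51) and havcr1 at 3.80-fold (2.01 to 7.43). Microglia or macrophage-like cells were also a larger share of the mutant library, 2.62% against 1.13%, and too few for a comparison within that class. Immediate early genes, which respond to neuronal activity and to stress, stood at 0.20 (0.13 to 0.37, percentile 98.8), with nr4a1 at 2.53-fold and junbb at 1.89-fold. They stood at 0.68 (0.52 to 0.78) in epidermis-like cells, with 20 of 22 members higher, and at 0.03 (-0.04 to 0.23) without barcodes over 10000 UMIs. In neuron-like cells alone the neurogenesis list stood at -0.23 and the immediate early list at -0.40, so neither direction held there. In epidermis-like cells, a class outside the nervous system, the neurogenesis list stood at 1.42 (1.13 to 1.90) with 17 of 17 members higher, and her4.4 was 28.0-fold higher. Whether these UMIs are expression in that class or transcripts of other cells was not tested. The neuropeptide list had a median of -0.80 (-1.02 to -0.44, percentile 0.03), while its summed CPM was slightly higher in the mutant (log2 0.14), with pomca and scg3 (2.77-fold) on the higher side.

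Of 5477 genes compared at 5 dpf, 216 were at least 2-fold higher and 213 at least 2-fold lower in the mutant library. Several of the genes standing furthest apart were pituitary, gut or pancreatic genes held by few barcodes. The hormone gene prl had 767 UMIs against 3 in wild type, a ratio of 501 (171 to 2435), and pomca, the melanocortin precursor, 342 against 8 (83.8-fold, 42.0 to 196). The mutant barcode with most UMIs of each gene held 41.9% of prl, 46.8% of pomca and 56.6% of mlnl (95.6-fold higher). For pvalb9 (15.3-fold) it held 62.0%, for myl4 (18.9-fold) 51.9% and for s100s (33.0-fold) most. Whether different genes shared such a barcode was not examined. The lipid carriers apoa1a and rbp2a were 14.8-fold and 10.8-fold higher. Spread more widely were rrm2, a ribonucleotide reductase subunit, with 391 against 96 UMIs over 108 mutant barcodes (7.98-fold, 6.37 to 10.1), and the MHC class I gene mhc1zea, with 96 against 18 UMIs over 59 barcodes (10.5-fold, 6.27 to 18.4).

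On the lower side the neuropeptide galanin gene galn had 128 UMIs in wild type and 0 in the mutant, at least 21.8-fold lower. Somatostatin, sst1.1, had 154 against 1 (ratio 0.0127, 0.000320 to 0.0720). The calcium sensors rcvrnb and cabp5b had 191 against 2 UMIs (ratio 0.0205, 0.00247 to 0.0752) and 172 against 2 (0.0228, 0.00274 to 0.0836), and pvalb5 was 14.9-fold lower. The pancreatic genes ela2, sycn.2, ela2l, prss59.2 and prss1 were 28.0-fold, 37.2-fold, 16.8-fold, 13.7-fold and 13.3-fold lower. Taken gene by gene, the wild-type barcode with most UMIs held 65.4%, 73.6%, 66.9%, 76.0% and 70.4% of them. Without barcodes over 10000 UMIs there were 131 genes higher and 125 lower, of which 89 and 85 were among the genes counted above.

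**Figure D1:**
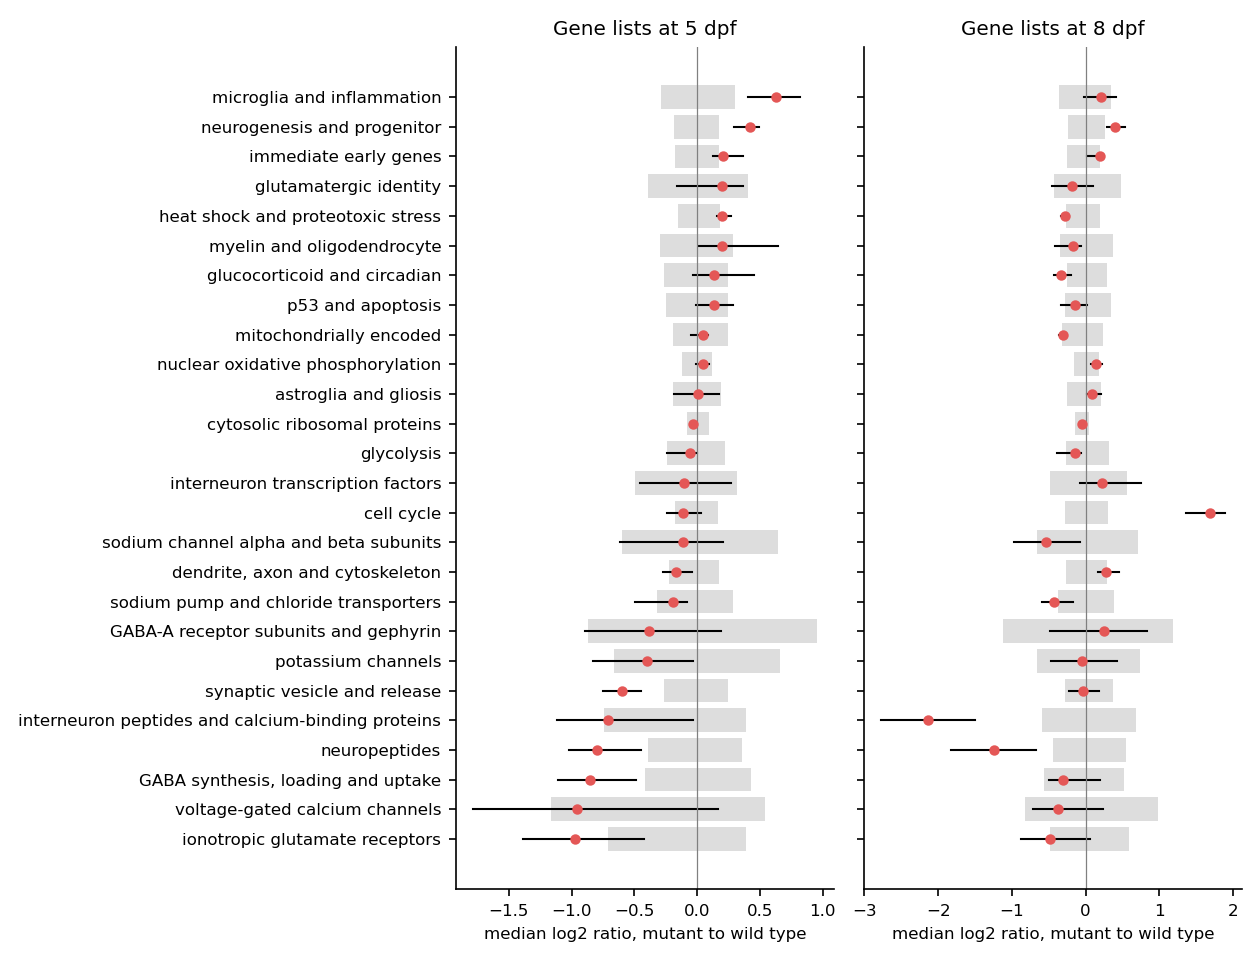
Median log2 ratio of mutant to wild type for 26 gene lists at 5 dpf (left) and 8 dpf (right), 1 library per group. Points are medians, black lines the 95% interval from counting error, and grey bars the central 95% of matched random lists. The cell cycle list lies at 1.68 at 8 dpf and the synaptic vesicle list at -0.60 at 5 dpf.

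The comparison at 8 dpf asks the same at the later age. Here the cell cycle genes stood apart. Of 26 measured members 25 were higher in the mutant library and 22 were at least 2-fold higher, with a median log2 ratio of 1.68 (1.37 to 1.89), above all random lists. The proliferation marker mki67 was 6.41-fold higher (4.85 to 8.62), the replication clamp pcna 4.83-fold (3.56 to 6.68) and top2a, a topoisomerase of dividing cells, 4.77-fold (2.86 to 8.39). The reductase gene rrm2 had 84 UMIs against 0, at least 25.8-fold higher. The list's median was 1.07 without barcodes over 10000 UMIs, still on the higher side. At 5 dpf the same list had a median of -0.11 (-0.24 to 0.03, percentile 11.1), with rrm2 the only member at least 2-fold apart.

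Neuropeptide genes were lower at 8 dpf, with a median of -1.24 (-1.82 to -0.68) and 9 of 12 members lower, but the median was 0.49 over members with at least 100 UMIs. The list of interneuron peptides and calcium-binding proteins stood at -2.13 (-2.78 to -1.50) with 5 of 6 members lower, among them the Purkinje cell parvalbumin pvalb7 (ratio 0.156, 0.116 to 0.207). At 5 dpf that list stood at -0.71 (-1.12 to -0.03) and pvalb7 itself was 1.67-fold higher, and with each cell weighted equally the list turned to 1.03. The neurogenesis list was again higher (0.40, 0.30 to 0.53, percentile 99.7, 24 of 29 members), but stood at -0.21 without barcodes over 10000 UMIs and at -0.08 with every cell weighted equally. Synaptic vesicle genes stood at -0.03 (-0.23 to 0.18, percentile 31.3) over all cells and at -0.53 without the large barcodes. The GABA list stood at -0.31 (-0.50 to 0.19, percentile 12.1) and the glutamate receptor list at -0.49 (-0.87 to 0.06, percentile 2.39). Immediate early genes stood at 0.20 (0.02 to 0.24, percentile 97.2) and turned to -0.11 with cells weighted equally. The microglia list stood at 0.21 (-0.02 to 0.41, percentile 90.4), with apoeb at a ratio of 0.387, and the ratio of its summed CPM was 0.609, the other direction.

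Of 4197 genes compared at 8 dpf, 249 were at least 2-fold higher and 223 at least 2-fold lower in the mutant. Many of the named genes were muscle genes, each held mainly by 1 barcode, and whether that barcode was the same was not examined. The mutant barcode with most UMIs of each gene held 84.5% of pvalb2 (32.2-fold higher), 87.8% of pvalb1 (32.9-fold) and 89.3% of tpma (26.5-fold). For tnni2b.2 (27.8-fold), mylpfa (13.9-fold) and mylpfb it held 85.1%, 89.6% and 88.4%, and for tnnt3b (10.3-fold) most. The gene mylpfb had 121 UMIs against 2 (ratio 55.8, 15.12 to 466). Without barcodes over 10000 UMIs mylpfa stood at 1.38 and tnnt3b at 1.298. The remaining higher genes had no such barcode: mhc1zea with 202 UMIs against 6 (31.1-fold, 14.0 to 85.6), the mucin gene mucms1 with 128 against 2 (ratio 59.0, 16.0 to 493), and the collagen gene col10a1a with 141 against 4 (32.5-fold, 12.4 to 121) in 5 barcodes.

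Lower in the 8 dpf mutant were slow and cardiac muscle genes, again held mainly by few wild-type barcodes. smyhc1 had 877 UMIs in wild type against 2 (ratio 0.00210, 0.000254 to 0.00762) and smyhc2 586 against 2 (0.00315, 0.000380 to 0.0114), with 73.8% and 51.7% in 1 barcode each. tnnt2e, actc1c, tnnc1b, myl13 and myl10 were 82.8-fold, 51.8-fold, 44.8-fold, 31.8-fold and 30.5-fold lower. The ratios of tnni1c, tnni1d and mybpc3 were 0.00738 (0.000185 to 0.0419), 0.0119 (0.00143 to 0.0437) and 0.00854 (0.000214 to 0.0486), each against 1 or 2 mutant UMIs. Without barcodes over 10000 UMIs 106 genes were higher and 127 lower, of which 90 and 79 were among those counted above. The higher genes made up 52.8% of the 2-fold genes in the main setting, 40.6% with each cell weighted equally and 41.9% among genes with at least 500 UMIs.

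Several fixed lists showed small or uneven differences. Sodium channel subunits stood at -0.11 at 5 dpf and -0.54 at 8 dpf, potassium channels at -0.40 and -0.05, and calcium channels at -0.96 and -0.38, with 8, 8 and 5 members measured at 5 dpf and 7, 7 and 4 at 8 dpf. GABA-A receptor genes stood at -0.39 and 0.25, interneuron transcription factors at -0.11 and 0.22 and glutamatergic identity genes at 0.20 and -0.19. The ratio of the summed CPM lay in the other direction from the median for calcium channels (1.08 and 1.02), interneuron transcription factors at 5 dpf (1.19), astroglia (0.949 and 0.963), glycolysis at 5 dpf (1.01), and at 8 dpf for potassium channels (1.02), the GABA list (1.06) and synaptic vesicle genes (1.03). The p53 and apoptosis list stood at 0.13 and -0.14, astroglia at 0.01 and 0.09, nuclear oxidative phosphorylation at 0.05 and 0.13 (-0.02 at 8 dpf in neuron-like cells), and glycolysis at -0.06 and -0.15 (0.02 at 8 dpf with cells weighted equally). Mitochondrially encoded genes stood at 0.05 and -0.31, and the sodium pump and chloride transporters at -0.19 and -0.43 (percentile 1.48). Glucocorticoid and circadian genes stood at 0.14 and -0.33 (percentile 0.53), with the clock gene per3 at 0.614 and 0.429. Cytosolic ribosomal protein genes stood at -0.03 and -0.05, and at 0.08 and 0.30 in neuron-like cells. That turn of sign is read against no difference and not against random lists of the same cells, so it may follow a shift of all genes there.

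The comparison of both ages asks which differences recur. It covered 3843 genes, and the ages share no library. Across genes, which are not independent replicates, the log2 ratios at 5 and 8 dpf were nearly unrelated (Pearson r 0.03, Spearman rho 0.03), and 49.0% of genes had the same sign at both. There were 28 genes at least 2-fold higher at both ages, where independent lists would give 8.36, and 23 lower, where they would give 4.63. However 40 genes were 2-fold apart in opposite directions, where 12.5 would be given.

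The heat shock gene hsp70l was the most abundant gene to recur. It was 2.53-fold higher at 5 dpf (2.43 to 2.63) and 2.57-fold at 8 dpf (2.49 to 2.65), spread over 521 to 737 barcodes in each library. Its relatives were less far apart over all cells: hsp70.1, hsp70.2 and hsp70.3, looked up after hsp70l had been seen, stood at 1.13, 0.928 and 1.23 at 5 dpf and 0.846, 0.823 and 0.826 at 8 dpf. In mural or fibroblast-like cells at 5 dpf hsp70.3 was 1.88-fold higher (1.64 to 2.15). Counts within such families are uncertain, because it is not recorded how reads shared by near-identical copies were assigned. Also higher at both ages were mhc1zea, her12 (6.93-fold and 5.53-fold), her15.2 (2.45-fold and 2.28-fold), the cerebellin gene cbln20 (3.47-fold and 2.67-fold), and the liver genes c9, ambp, apoa1b, apoa2 and tfa. These liver genes were 2.93-fold to 7.48-fold higher at 5 dpf and 2.29-fold to 4.35-fold at 8 dpf. For each of them the top mutant barcode at 8 dpf held most UMIs, although their ratios there stayed above 2-fold without barcodes over 10000 UMIs.

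The genes named as lower at both ages were of mixed kinds. The keratin krt96 was 13.9-fold and 23.6-fold lower, the otolith gene stm 2.84-fold and 2.81-fold, anxa1b 3.12-fold and 3.08-fold, and the cornified envelope gene ppl 2.53-fold and 2.67-fold. The sodium pump subunit atp1b1b was 2.85-fold and 2.07-fold lower, ttn.2 2.52-fold and 2.86-fold, pdia6 2.61-fold and 2.49-fold, agr1 2.02-fold and 2.19-fold and ifitm1 2.09-fold at both. krt15, ranked by its bounds, was 1.74-fold and 3.80-fold lower, and its 5 dpf ratio was 1.001 with cells weighted equally. A clone-named gene outside the naming rule, si:ch211-114n24.6, singled out after its values were seen, stood at 0.116 (0.0899 to 0.148) and 0.164 (0.122 to 0.217).

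**Figure D2:**
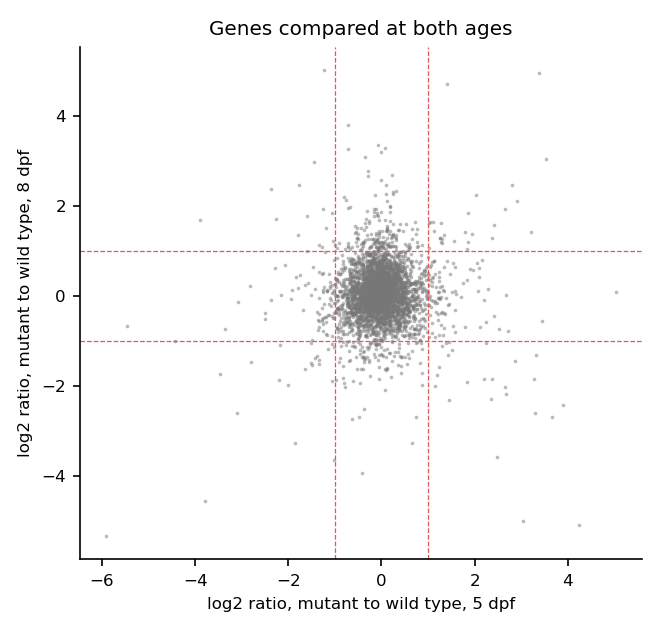
Log2 ratio of mutant to wild type at 5 dpf (x axis) against 8 dpf (y axis), 1 point per gene compared at both ages with UMIs in all 4 libraries. Dashed lines mark 2-fold. The cloud shows no slope (Pearson r 0.03).

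The cell class comparison asks whether the composition of the captured cells differs. Neural progenitor-like cells made up a larger share in the mutant at both ages, 15.7% (13.1 to 18.6) against 11.8% (10.1 to 13.8) at 5 dpf and 6.19% (4.69 to 7.98) against 3.83% (2.70 to 5.26) at 8 dpf. The share ratios were 1.33 (1.03 to 1.71) and 1.62 (1.04 to 2.53). Without barcodes over 10000 UMIs the 5 dpf ratio was 1.001, and with the stricter filter on cells the 8 dpf ratio was 1.02. Cells were clustered and named anew in both settings. Without the large barcodes the class held 133 mutant and 225 wild-type cells at 5 dpf, against 114 and 146 in the main setting. Cells thus changed class, and the change of ratio cannot be put down to the large barcodes themselves. Among named classes only, the ratios were 1.199 (0.930 to 1.54) and 1.23 (0.795 to 1.93). Microglia or macrophage-like cells were 2.62% against 1.13% at 5 dpf (ratio 2.31, 1.098 to 4.98) and 2.14% against 1.17% at 8 dpf (1.83, 0.826 to 4.25). Among named classes only, the 5 dpf ratio was 2.08 (0.990 to 4.49).

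Neuron-like cells were 20.97% (18.1 to 24.1) in the mutant and 19.2% (17.0 to 21.5) in wild type at 5 dpf, and 15.6% against 13.6% at 8 dpf. Within this class, however, clusters 6 and 34, marked by gad1b, vgf and sypb and by nefma, chgb and vgf, held 8 and 3 mutant cells against 39 and 32 wild-type cells at 5 dpf, and 5 and 4 against 10 and 13 at 8 dpf. Radial glia-like cells were 4.55% against 4.54% at 5 dpf and 8.999% against 7.13% at 8 dpf. Hair or supporting cell-like cells were 0.414% (0.0854 to 1.204) against 1.62% at 5 dpf and 5.85% against 3.83% at 8 dpf. Their order turned to 2.21% against 1.78% at 5 dpf at Leiden resolution 0.5. Endothelial-like cells were 1.24% against 2.51% and 0.675% against 0.638%. Epidermis-like cells were 14.2% against 12.4% and 10.2% against 7.98%, and mural or fibroblast-like cells 11.4% against 11.8% and 11.6% against 7.77%. With at least 600 UMIs and 400 genes per cell the order of the genotypes at 8 dpf turned for several classes: neuron-like cells (13.96% against 16.5%), radial glia-like (9.75% against 10.7%), epidermis-like (12.05% against 13.5%), hair or supporting cell-like (6.50% against 7.36%), oligodendrocyte lineage-like (3.44% against 4.31%), microglia or macrophage-like (1.91% against 2.03%) and endothelial-like cells (0.382% against 1.52%). At 5 dpf neuron-like (14.7% against 17.4%) and radial glia-like cells (3.68% against 6.12%) turned, as did cartilage or bone-like cells (2.30% against 1.998%). Unnamed cells were then 20.9% against 18.0% at 5 dpf and 20.7% against 15.5% at 8 dpf. Cells were clustered and named anew under this filter, and some changed class. Neural progenitor-like cells at 8 dpf numbered 73 in the mutant and 54 in wild type, against 55 and 36 in the main setting. The shares therefore depend on this setting, and the shallow cells and the new naming cannot be told apart. Oligodendrocyte lineage-like cells were 2.07% against 1.94% and 2.25% against 2.13%, cartilage or bone-like cells 2.07% against 2.11% and 3.26% against 2.87%, and muscle-like cells 1.38% against 0.891% and 0.450% against 0.851%. The oligodendrocyte share at 5 dpf depended on the clustering. It was 0.276% against 1.13% at Leiden resolution 0.5 and likewise lower in the mutant in 4 other settings in which cells were clustered anew. Among named classes only, the ratio was 0.959. Cluster 27 of this class held 2 mutant and 14 wild-type cells at 5 dpf. Digestive gland-like cells were 1.103% against 0.486% and 0.675% against 0.213%, and erythrocyte-like cells 0.828% against 0.405% and 0.562% against 0.213%. Unnamed clusters held 21.4% against 29.1% at 5 dpf and 31.5% against 47.8% at 8 dpf, and a single shallow cluster with a median of 410 UMIs held 28.6% of the 8 dpf wild-type cells.

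**Figure D3:**
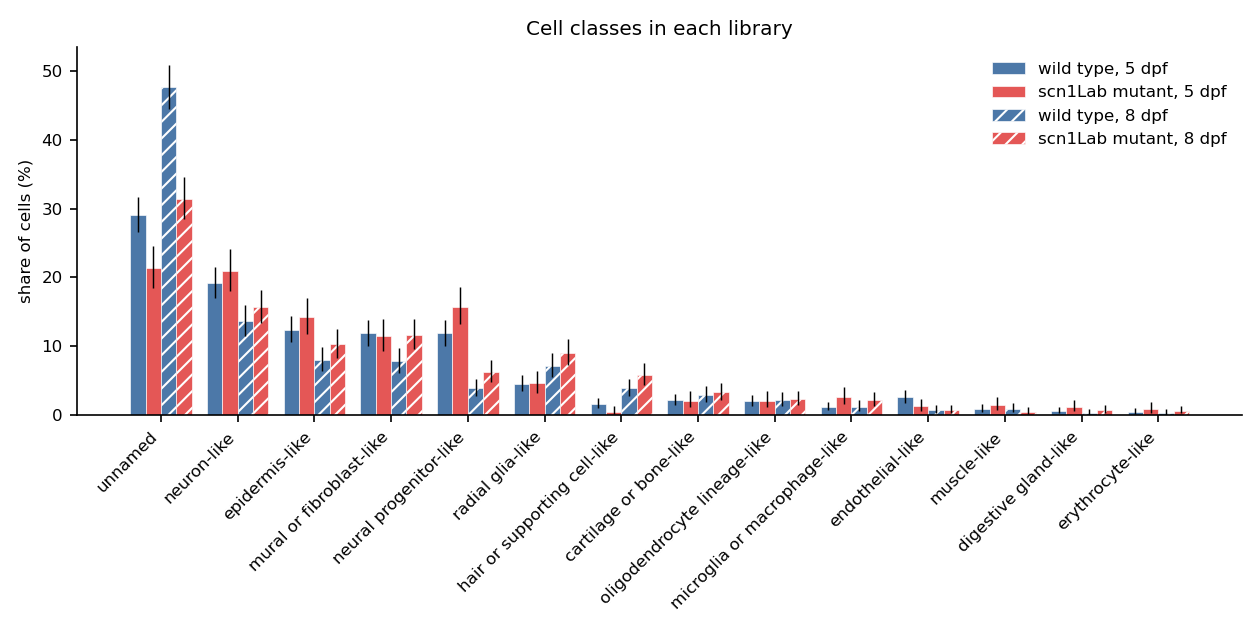
Share of cells (%) in each cell class for the 4 libraries, with 95% binomial intervals that cover counting error only. Progenitor-like cells stand at 15.7% in the 5 dpf mutant and 3.83% in the 8 dpf wild type, and unnamed cells reach 47.8% in the 8 dpf wild type.

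The ratio of inhibitory to excitatory markers bears on the balance that is of interest in epilepsy. UMIs of gad1b, gad2 and slc32a1 were set against UMIs of slc17a6a, slc17a6b and slc17a7a, which load glutamate into vesicles. At 5 dpf the ratio was 3.75 (3.09 to 4.58) in wild type, from 491 and 131 UMIs, and 2.56 (1.84 to 3.60) in the mutant, from 133 and 52. At 8 dpf it was 1.75 (1.29 to 2.39) in wild type and 1.98 (1.42 to 2.79) in the mutant, so the order of the genotypes was the opposite and the intervals overlapped at both ages. With gad1b against slc17a6b alone the ratios were 1.11, 0.720, 0.568 and 0.511 for wild type and mutant at 5 dpf, then mutant and wild type at 8 dpf.

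Neuron-like cells with a UMI of a GABAergic marker made up 27.4% (21.8 to 33.6) in wild type and 16.4% (10.9 to 23.3) in the mutant at 5 dpf, and 16.4% and 12.9% at 8 dpf. The shares in epidermis-like cells, which should lack these genes, were 3.92%, 1.94%, 0% and 0% in that order. Median depths in that order were 1043, 661, 784 and 866 UMIs in neuron-like cells and 1636, 1623, 2016 and 2021 in epidermis-like cells. The 0 of 75 and 0 of 91 epidermis-like cells at 8 dpf rest on few cells. With neuron-like cells thinned to 500 UMIs the GABAergic shares were 15.9% (11.2 to 21.6) and 13.0% (7.49 to 20.6) at 5 dpf and 9.71% and 8.70% at 8 dpf, so a difference was not detectable at equal depth. Thinning left out the cells under 500 UMIs, 29 of 237 and 37 of 152 at 5 dpf and 25 of 128 and 24 of 139 at 8 dpf, wild type first. Cells with a glutamatergic marker UMI made up 13.9% (9.78 to 19.0) and 7.24% (3.67 to 12.6) of neuron-like cells at 5 dpf and 12.5% and 9.35% at 8 dpf, against 1.31%, 0%, 0% and 1.099% of epidermis-like cells in that order. After thinning they were 6.73% and 6.09% at 5 dpf and 10.7% (5.45 to 18.3) and 2.61% (0.541 to 7.43) at 8 dpf.

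**Figure D4:**
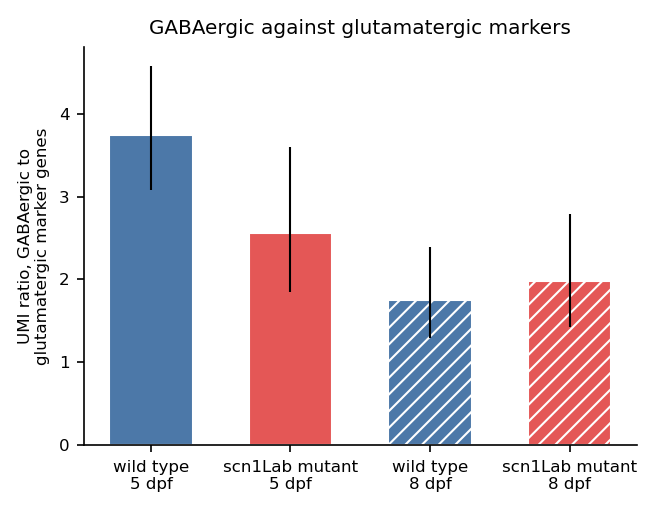
Ratio of GABAergic to glutamatergic marker UMIs in the 4 libraries, with exact 95% intervals. The 5 dpf bars stand at 3.75 for wild type and 2.56 for the mutant.

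Within neuron-like cells hsp70l was higher in the mutant at both ages, while the heat shock list lay inside the central 95% of matched random lists at both. hsp70l was 4.13-fold higher at 5 dpf (3.73 to 4.57) and 3.06-fold at 8 dpf (2.77 to 3.39), and the list stood at 0.39 (0.32 to 0.72, percentile 96.3) and 0.05 (-0.09 to 0.29, percentile 42.5). At 5 dpf its co-chaperone dnaja1 was 4.98-fold higher (2.80 to 8.99), with ubb, a ubiquitin gene, at 3.61-fold, tuba1c at 3.76-fold and pcm1 at 4.11-fold. At 8 dpf the immediate early genes fosab and junbb were 4.08-fold (3.06 to 5.53) and 3.80-fold (2.32 to 6.52) higher, followed by hmgb2a at 4.35-fold and sumo3a at 2.87-fold. Such genes as fosab and junbb respond to neuronal activity and to stress, and which of these applies was not tested. Synaptic vesicle genes were lower in this class at both ages, with medians of -0.57 (-0.80 to -0.23) and -0.53 (-0.88 to -0.29), and snap25a was 2.62-fold lower at 8 dpf. The make-up of the class differed, however, with fewer mutant cells in clusters 6 and 34, and in cluster 1 alone the 5 dpf median was 0.57 (0.11 to 0.76). Lists of other cell types were lower in the class at 5 dpf as well, astroglia at -1.58 and myelin at -2.11, so these medians need not be differences within a cell type. Mitochondrially encoded genes stood at -0.42 and -0.45.

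Other genes lower in mutant neuron-like cells at 5 dpf were sst1.1, the Wnt modulator sfrp2, fabp7b and the neurofilament gene nefma, with 100, 144, 87 and 85 UMIs in wild type and 0 in the mutant. They were at least 9.74-fold, 14.0-fold, 8.48-fold and 8.28-fold lower. The gene nefma is a leading gene of cluster 34, which held 32 wild-type and 3 mutant cells, so the make-up of the class enters these values. col10a1a, a collagen gene, had 501 UMIs against 1, a ratio of 0.00683 (0.000173 to 0.0382). Clusters 1 and 34 of the class held 1 and 4 barcodes over 10000 UMIs over the 4 libraries. Whether such barcodes held the col10a1a UMIs was not examined, so this value need not be a difference in neurons. At 8 dpf sncgb, kmt2a, spen and histh1l were 3.75-fold, 3.38-fold, 3.36-fold and 2.55-fold lower. Of 1442 genes compared in neuron-like cells at 5 dpf, 77 were at least 2-fold higher and 158 lower, and of 691 at 8 dpf, 19 and 38.

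In epidermis-like cells mucms1 had 49 UMIs against 1 at 5 dpf (ratio 78.5, 13.4 to 3163) and 101 against 0 at 8 dpf, at least 51.2-fold higher. The gut hormone gene mlnl had 240 against 1 at 5 dpf (ratio 384, 68.3 to 15246), and krt96 was 17.3-fold and 14.1-fold lower at the 2 ages. Over all cells of the 5 dpf mutant library 1 barcode held most of the mlnl UMIs. Clusters 7, 9, 10 and 26 of this class held 12, 8, 16 and 3 barcodes over 10000 UMIs over the 4 libraries. Without such barcodes fewer genes of the class were 2-fold apart, so a few large barcodes enter these values. Actinotrichia genes and2 and and3 were 8.39-fold and 8.70-fold higher at 8 dpf, and the complement factor cfd 39.6-fold lower. In mural or fibroblast-like cells hsp70l was 4.29-fold and 2.46-fold higher, col1a1a was 2.84-fold higher at 8 dpf, and col2a1a 4.69-fold lower at 5 dpf. In epidermis-like cells 184 of 2496 genes were 2-fold higher and 162 lower at 5 dpf, and 89 and 122 of 1261 at 8 dpf. In mural or fibroblast-like cells these were 27 and 39 of 679, and 20 and 35 of 396.

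Between the ages, cell cycle genes were far lower at 8 dpf in both genotypes, with medians of -3.11 (-3.35 to -2.86) in wild type and -1.47 (-1.55 to -1.30) in the mutant, below all random lists in both. Nuclear oxidative phosphorylation genes stood at -1.005 and -0.86, and ribosomal protein genes at 0.30 and 0.29. Circadian genes stood at 1.07 in wild type and 0.40 in the mutant (percentiles 100 and 99.98). Synaptic vesicle genes stood at -0.92 in wild type (percentile 0.72) and at -0.22 in the mutant, where random lists had a median of -0.26 (percentile 58.6). In wild type the named genes higher at 8 dpf were muscle genes: myl10 (240.4-fold), smyhc2 (242-fold) and tnnt2e (139-fold), with actc1c at 478 UMIs against 1 (ratio 790, 141 to 31257) and tnnc1b at 413 against 2 (341, 93.8 to 2827). tnni2a.1 and kif4, a mitotic kinesin, were at least 89.4-fold and 38.7-fold lower. col10a1a was 181-fold lower, myhb 47.3-fold, and kpna2 had 3 UMIs against 411 (ratio 0.0121, 0.00248 to 0.0355).

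In the mutant pvalb2, myhz1.1 and pvalb8 were 43.3-fold, 46.9-fold and 18.0-fold higher at 8 dpf, with myhz1.2 at 298 UMIs against 2 (ratio 116, 31.8 to 961) and tspan1 at 181 against 3 (46.9, 15.8 to 230). The pituitary genes prl and tshba were at least 329-fold and 31.7-fold lower and pomca 110.0-fold lower, while tnni2a.1 and actc1a had ratios of 0.00374 (0.0000942 to 0.0211) and 0.00587 (0.000707 to 0.0214). In wild type 514 of 5573 genes were 2-fold higher and 1369 lower at 8 dpf, and in the mutant 260 and 604 of 4265. The median of all genes was -0.33 in wild type and -0.26 in the mutant, against -0.04 and -0.03 with a median of ratios size factor, which gave 758 higher and 940 lower in wild type and 379 and 369 in the mutant. The higher share of the 2-fold genes was 27.3% and 30.1% in the main setting and 44.6% and 50.7% with that factor. The ages may have been prepared and sequenced separately, so age and batch cannot be told apart.

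Fish homozygous for a mutation also share the haplotype around it, so genes near scn1lab were examined by gene order in GRCz12tu. Of the 200 protein-coding genes on each side, 53 were compared. Their mean absolute log2 ratio was 0.48 at 5 dpf, inside the 0.28 to 0.53 of matched random genes (percentile 91.6), and 0.47 at 8 dpf, inside 0.35 to 0.63 (percentile 47.4). The sign was the same at both ages for 41.5% of them, against 49.0% of all genes, and for 60.0% of the 15 compared within 50 genes and 54.5% of the 33 within 100. Within 100 genes the mean shared log2 ratio was 0.21 (percentile 96.4), inside the 0.05 to 0.22 of random genes. A single neighbour, si:ch211-114n24.6, was 2-fold apart the same way at both ages. The gene sumo3a, named above in neuron-like cells at 8 dpf, is also a neighbour, 19 genes from scn1lab, and was less than 2-fold higher over all cells at both ages.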

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

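The tests chosen after the result was seen are those of barcodes over 10000 UMIs, of genes that vary between any libraries, of the haplotype and of the dendrite and axon list. The joint cell cycle test and the test without clusters 6, 34 and 35 were added once earlier tests of the same patterns had been seen, and all cluster numbers come from these data.

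The list of dendrite, axon and cytoskeleton genes was lower in the mutant at 5 dpf (-0.17) and higher at 8 dpf (0.28). The heat shock list was higher at 5 dpf (0.20) and lower at 8 dpf (-0.28), although hsp70l itself was higher at both. The myelin and oligodendrocyte list stood at 0.20 at 5 dpf, where plp1b was 4.62-fold higher, and at -0.18 at 8 dpf. Cluster 27, with plp1b among its leading genes, went the other way at 5 dpf, with 2 mutant and 14 wild-type cells. In the main setting each of these 3 lists lay in opposite directions at the 2 ages, and that difference was not tested, since each group is 1 library. None of the 3 held in every setting. The dendrite and axon list at 8 dpf stood at -0.34 without barcodes over 10000 UMIs, and the myelin list at 5 dpf stood at -0.33 with each cell weighted equally. The heat shock list at 8 dpf stood at 0.0546 in neuron-like cells.

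Barcodes under the cell filter also held scn1lab UMIs, 7 in wild type at 5 dpf, 5 in the mutant at 5 dpf, 6 in the mutant at 8 dpf and 11 in wild type at 8 dpf. The main comparisons did not use those barcodes. UMIs on the mitochondrial contig outside its named genes, which no comparison examined, made up 13.7% in wild type at 5 dpf, 11.5% in the mutant at 5 dpf, 15.4% in the mutant at 8 dpf and 13.7% in wild type at 8 dpf.

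Cell cycle genes were higher in the mutant at 8 dpf (1.68). Without barcodes over 10000 UMIs the median was 1.07 (0.82 to 1.35), which argues against a few large barcodes as the whole source. Without the dividing progenitor clusters 8 and 21 it was 1.63 (1.33 to 1.86), which argues against the cells counted in those clusters as the whole source. Without both it was 1.16 (0.75 to 1.47). Clusters 8 and 21 held only 13 and 7 mutant and 5 and 2 wild-type cells at 8 dpf. Other cells with replication genes stayed in, as in cluster 3 with mcm2 among its leading genes, so more dividing cells in general are left open. In neuron-like cells alone the list was also higher, by more than over all cells, as given below. Whether those UMIs are expression in that class or transcripts of other cells was not tested. A difference in proliferation linked to the genotype, a difference in the age or stage of the sampled fish, and a difference between preparations may each remain, and 1 library per group cannot separate them.

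Synaptic vesicle genes were lower in the mutant at 5 dpf (-0.60). The dendrite, axon and cytoskeleton list stood at -0.17 (-0.26 to -0.05), but only 5220 of its 15893 wild-type UMIs lay in neuron-like cells, over the members measured in each. It therefore leaves open a lower share of neurons in general. The neuron-like share at 5 dpf was 20.97% in the mutant against 19.2% in the main setting, and 14.7% against 17.4% with at least 600 UMIs and 400 genes per cell. Clusters 6, 34 and 35 were split from 1 cluster because its leading genes held more markers of another class than of its best name. Cluster 35 joined neuronal and digestive markers. Over all cells outside these clusters the median was -0.083 (-0.23 to 0.16), so fewer captured cells of those clusters are a candidate explanation. Its limit is that such genes helped to define them. In cluster 1 alone the median was 0.57 (0.11 to 0.76), on the higher side and outside both outcomes written down for that test, which leaves the narrower version with clusters 6 and 34 open. Whether fewer cells of clusters 6, 34 and 35 were present in the mutant brain or fewer were recovered was not tested.

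Genes that were 2-fold apart the same way at both ages were 3.93 times as many as independent lists would give, and genes apart in opposite directions 3.21 times as many. Much of the recurrence may therefore come from genes that vary between any libraries. The haplotype around scn1lab held 1.96% of the recurring genes, 1 of 51, which argues against it as the source of the group. A lasting effect of the genotype on single genes such as hsp70l and mhc1zea was not tested, and mhc1zea is of a family that differs between haplotypes.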

How the results depend on the processing

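The settings chosen only after results had been seen are those without barcodes over 10000 UMIs, with each cell weighted equally, without cells over 25% with the mitochondrial contig counted, and with shares among named classes. In all 896 alternatives of 111 results were computed: 706 stayed, 160 moved and 30 turned direction. A ratio or list value stayed when it lay inside the counting interval of the main value. It turned only where that interval left out no difference and the value lay on the other side. A change of side can therefore count as stayed or moved, as for some class shares above. Counts of genes could only stay or move. Of 308 alternatives of the leading results, 229 stayed, 71 moved and 8 turned. The cause was not tested for any of them. No paired analysis was run, since each group is 1 library and no replicate error could be estimated. The ages and the batches of preparation cannot be separated. Below, main values stand in brackets and lists are given as the median log2 ratio of mutant to wild type. List values here are read against no difference and not against random lists of the same cells, so a change of sign may follow a shift of all genes.

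Genes 2-fold higher and lower at 5 dpf (216 and 213) numbered 131 and 125 without barcodes over 10000 UMIs, 1043 and 1185 with at least 20 UMIs over the 2 libraries and 42 and 42 with at least 500. The lower genes numbered 425 with libraries re-weighted to equal class shares and 322 with each cell weighted equally. At 8 dpf (249 and 223) they numbered 106 and 127 without the large barcodes, 1231 and 1095 at 20 UMIs and 39 and 54 at 500, and the lower ones 342 re-weighted and 350 with cells weighted equally. Genes higher at both ages (28) numbered 17 without the large barcodes, 159 at 20 UMIs and 6 at 500. Genes lower at both ages (23) numbered 40 re-weighted, 42 with cells weighted equally, 172 at 20 UMIs and 7 at 500. Between ages, 283 and 862 genes of wild type (514 and 1369) and 124 higher genes of the mutant (260) were left without the large barcodes, and 369 lower genes of the mutant (604) with the median of ratios.

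In neuron-like cells only, the scn1lab ratio at 5 dpf was 2.44 (0.980). The 5 dpf lists there were GABA synthesis, loading and uptake -1.29 (-0.85), dendrite, axon and cytoskeleton 0.0274 (-0.17), immediate early genes -0.40 (0.20), cell cycle -0.30 (-0.11), neurogenesis and progenitor -0.23 (0.42), myelin and oligodendrocyte -2.11 (0.20), neuropeptides -1.82 (-0.80) and cytosolic ribosomal proteins 0.0832 (-0.03). The 8 dpf lists there were synaptic vesicle and release -0.53 (-0.03), dendrite, axon and cytoskeleton -0.13 (0.28), heat shock and proteotoxic stress 0.0546 (-0.28), cell cycle 1.91 (1.68), neurogenesis and progenitor 0.17 (0.40), nuclear oxidative phosphorylation -0.0197 (0.13), neuropeptides -2.12 (-1.24) and cytosolic ribosomal proteins 0.30 (-0.05).

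With each cell weighted equally, the 5 dpf lists were interneuron peptides and calcium-binding proteins 1.03 (-0.71), synaptic vesicle and release -0.34 (-0.60), cell cycle -0.38 (-0.11) and myelin and oligodendrocyte -0.33 (0.20). The median log2 ratio of the list dendrite, axon and cytoskeleton, mutant vs wild type, 5 dpf was then 0.000528 (-0.17). The 8 dpf lists were GABA synthesis, loading and uptake -0.56 (-0.31), synaptic vesicle and release -0.41 (-0.03), dendrite, axon and cytoskeleton -0.15 (0.28), immediate early genes -0.11 (0.20), glycolysis 0.0216 (-0.15), neuropeptides -0.59 (-1.24) and cytosolic ribosomal proteins 0.22 (-0.05), and the median log2 ratio of the list neurogenesis and progenitor, mutant vs wild type, 8 dpf was -0.0843 (0.40).

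The 8 dpf lists without barcodes over 10000 UMIs were GABA synthesis, loading and uptake -0.55, synaptic vesicle and release -0.53, dendrite, axon and cytoskeleton -0.34, cell cycle 1.07, neurogenesis and progenitor -0.21 and cytosolic ribosomal proteins 0.0806. As the ratio of the summed CPM, the 5 dpf lists were cell cycle 0.12 and neuropeptides 0.14, the median log2 ratio of the list cytosolic ribosomal proteins, mutant vs wild type, 5 dpf became 0.0190, and the 8 dpf lists were heat shock and proteotoxic stress 0.0146, cell cycle 1.301, neurogenesis and progenitor 0.23 and neuropeptides -0.32. With at least 600 UMIs and 400 genes per cell, the 8 dpf lists were neurogenesis and progenitor 0.57 and neuropeptides -0.39, and the median log2 ratio of the list myelin and oligodendrocyte, mutant vs wild type, 8 dpf was 0.00692 (-0.18). Over members with at least 100 UMIs, neuropeptides at 8 dpf stood at 0.49. Without cells over 25% with the mitochondrial contig counted, synaptic vesicle and release at 5 dpf stood at -0.44.

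For the share ratios here cells were clustered and named anew, except for those among named classes. The share ratio of hair or supporting cell-like cells at 5 dpf (0.255) was 1.24 at Leiden resolution 0.5 and 1.27 without the large barcodes. The ratio of neural progenitor-like cells was 1.001 at 5 dpf (1.33) without the large barcodes and 1.02 at 8 dpf (1.62) with at least 600 UMIs and 400 genes. With that filter neuron-like cells stood at 0.848 (1.09) and 0.846 (1.15) and radial glia-like cells at 5 dpf at 0.601 (1.003). Among named classes the neuron-like ratio at 8 dpf was 0.876. With gad1b against slc17a6b, the marker ratios were 1.11 (3.75), 0.720 (2.56), 0.568 (1.98) and 0.511 (1.75) for wild type and mutant at 5 dpf and mutant and wild type at 8 dpf.

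Genes 2-fold higher and lower in neuron-like cells at 5 dpf (77 and 158) numbered 39 and 57 at Leiden resolution 2, 34 and 61 with at least 600 UMIs and 400 genes and 49 and 94 without the large barcodes. The lower ones at 8 dpf (38) numbered 20 at resolution 2 and 12 with the stricter filter. In mural or fibroblast-like cells at 5 dpf 22 were lower (39) at resolution 2 and 17 higher (27) with the stricter filter. In epidermis-like cells 75 were higher and 56 lower at 5 dpf (184 and 162), and 44 and 53 at 8 dpf (89 and 122), without the large barcodes.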

Other observations

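The tests behind these values were chosen in part after the data were seen: the clusters held mainly by 1 library and the leading genes of cluster 35 were looked at only then.

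Some clusters were spread unevenly over the libraries. Cluster 21, mitotic progenitor-like cells with rx3, a gene of the early hypothalamus and retina, among its leading genes, held 29 mutant and 9 wild-type cells at 5 dpf and 7 mutant and 2 wild-type cells at 8 dpf. Cluster 31, an unnamed cluster with rad51c and cbln20 among its leading genes, held 13 cells of the 5 dpf mutant and 3 cells of the other libraries together. Cluster 32, with sp6, fgf18b and bmp2b, held 16 cells, all from the 8 dpf mutant.

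Cluster 35 joined neuronal and digestive markers, with galn, ela2, rcvrnb, sycn.2 and ela2l among its leading genes, and held 31 wild-type and 6 mutant cells at 5 dpf. Those 5 genes are also among the 10 named as lowest in the mutant at that age. An olfactory neuron cluster led by cnga4, ompb and pvalb5 held 34 wild-type and 6 mutant cells at 5 dpf, and 11 and 25 at 8 dpf. Values of 3 further lists in neuron-like cells at 5 dpf were -1.16 for the sodium pump and chloride transporters, -0.98 for glycolysis and -1.58 for astroglial genes.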
